A study of Mus musculus with 36 samples.

How the data were processed

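Polyadenylated RNA of mouse HM1 cells was sequenced at 12 time points with 3 biological replicates each, 36 libraries in all. Per the labels' protocols, feeder cells were removed before plating, RNA was extracted with a Qiagen RNeasy Plus Micro kit, libraries were made with a KAPA mRNA kit, and the medium was changed daily. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.20.0 and quantified with RSEM against GRCm38. The aligner, the annotation release and whether counting used strand are not given in the sources used here. By the exons of GENCODE M21, leaving out small RNAs, the named genes Aars, BC024139, Elavl3, Exosc6, Mobp, Onecut1 and Pcp4 share sequence with another gene on the same strand, and their values are uncertain. So are those of genes that share exon sequence with a gene on the other strand, which are Axin2, Bcas1, Ccnd1, Dll1, Evx1, Evx1os, Gli1, Gli3, Grm7, Hes5, Hoxb3, Hoxb5, Irx3, Lhx3, Lin28a, Nefl, Neurog3, Nfia, Nkx1-2, Nkx2-2, Pdgfra, Pou5f1, Rarb, Rps2, Shh, Tnr and ccdc198. Genes that overlap only in introns are not listed.

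The authors deposited RSEM expected counts per gene, which are estimated and need not be whole (6.87% of the values were not), and a second table of abundance in TPM. Each column of the deposited TPM table summed to between 999999.21 and 1000000.98. TPM corrects for gene length and for the total, so it gives shares of the transcripts in a library, and a change in one abundant group of transcripts moves the rest. Of 51912 gene IDs, 51633 matched a symbol in the mouse name table, and the matched genes held 99.925% of the counts. Coordinates come from GENCODE M21 on GRCm38 and count from 1.

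Expected counts were rounded to whole numbers. Genes were kept with edgeR's filterByExpr by time point, which left 17990 of the 32047 genes with at least 1 count. All 36 libraries entered 1 model with 12 groups, TMM scaling (factors 0.924 to 1.06) and 24 residual degrees of freedom, fitted with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3. The 4 pairs of neighbouring stages were compared, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are given with an approximate standard error, and levels as mean ± SD of TPM over 3 replicates. That error is the size of the log2 fold change divided by the square root of the test's F value. It is not a direct estimate, and it can be too small where a time point is near 0 counts. For a gene at 0 counts in 1 time point, the fold is a lower bound against 3 counts per library. For a gene with 1 to 3 counts in a time point, the ratio of summed counts scaled by library size has a 95% interval for counting error only, and reads without molecular identifiers are not independent molecules.

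The design, 39 gene lists for cell states, signals, housekeeping groups and other cell types, the named-gene rule and most alternatives were fixed before the data were examined. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 156 tests, of which 74 passed. With an estimated correlation 37 passed, and a list that lost its call has that p beside it. Named genes were a fixed panel of 15 per comparison, the 6 largest rises and 6 largest falls among changed genes whose groups did not overlap and whose higher group had a mean of at least 10 CPM (leaving out genes without a symbol and predicted Gm and Rik genes), and up to 4 changed members of each list that passed. Some of the list members were left out of the text for length, and single-gene results for some others are not reported here or counted among the values under the alternatives.

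Library totals ran from 26567321 to 35757989 counts. Mitochondrial genes took 0.949% to 1.92% of the counts, and the 10 most abundant genes of a library 4.23% to 7.37%. Replicates differed by more than sampling noise in every pair (chi-square per degree of freedom 3.13 to 54.4), and 0 pairs were identical, so each library counted once. The same fit was tested on simulated data for the real genes, drawn from the type of model that was fitted. Each gene had 1 level over all time points, and 200 of 17990 genes were changed, 66 or 67 for each fold. In the real comparisons most genes were called, so the shares below need not hold for those calls. For day 0.5 against day 0 it recovered 64.2% of 1.5-fold, 77.6% of 2-fold and 86.4% of 4-fold changes, with 3.18% of calls false. For day 2 against day 0.5 these were 67.2%, 80.6%, 95.5% and 4.14%, for day 4 against day 2 they were 58.2%, 79.1%, 87.9% and 3.23%, and for day 7 against day 4 they were 68.7%, 79.1%, 90.9% and 5.92%.

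The alternatives were median-of-ratios scaling, DESeq2 1.42.0, no filter on low counts, only the 6 libraries compared, the replicate number as a block, each replicate left out, limma on log2 of the deposited TPM plus 1 or plus 0.1, and for the lists an estimated correlation and fry. A fit without the libraries of days 1.5, 2.5 and 3.5, and day 1 in place of day 0.5, were added after seeing the data.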

Results

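Polyadenylated RNA was measured by sequencing in mouse HM1 embryonic stem cells that were carried from a neuromesodermal progenitor state towards motor neurons. Neuromesodermal progenitors are cells of the tail end of the embryo that give rise to spinal cord and to paraxial mesoderm. From day 0 the cells received 100 nM retinoic acid, a vitamin A derivative that patterns the hindbrain and spinal cord, and 500 nM SAG, a small molecule that switches on the Hedgehog pathway through Smoothened. The 36 libraries covered 12 time points (days 0, 0.5, 1, 1.5, 2, 2.5, 3, 3.5, 4, 5, 6 and 7) with 3 biological replicates each, and the day 0 libraries were taken as the control. Library totals ran from 26567321 to 35757989 counts. The labels do not say whether the 3 replicates came from separate cultures, so p-values measure the spread between these samples, which may in part be technical. The 4 comparisons below follow neighbouring stages of the course, and 17990 genes were tested in each with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment.

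Marker genes were highest at different times, given here as mean TPM with SD over 3 replicates. The order was not that of the stages throughout, since the progenitor factors Sox2 and Nkx2-2 were highest after the motor neuron genes. T, the Brachyury gene of caudal epiblast, was highest at day 0 (37.2 ± 2.86). Pax6 and Irx3, neural progenitor transcription factors, were highest at day 0.5, and Nkx6-1, a ventral spinal cord factor, at day 1. Olig2, which marks motor neuron progenitors, was highest at day 2 (180 ± 15.4). Its mean was 15.9 ± 1.95 at day 5 and 45.4 ± 1.90 at day 7. Neurog2 and Isl1 were highest at day 2.5, with Isl1 at 76.2 ± 5.34, and Mnx1, Lhx3 and Chat at day 3, with Mnx1 at 28.7 ± 2.51. Tubb3, a neuronal tubulin, was highest at day 5. Foxa2, Shh, Sim1, Sox9, Nkx2-2 and Sox2 were highest at day 6, with Shh at 410 ± 26.1, and Nfia and Fabp7 at day 7, with Nfia at 95.8 ± 3.03. In CPM the highest mean moved to day 1 for Sox2, day 1.5 for Olig2 and day 5 for Nkx2-2. Without replicate 2 it moved to day 5 for Sox2 and day 3 for Neurog2, and without replicate 3 to day 5 for Sox2 and day 7 for Nkx2-2 and Sim1. No test was made of these days. The root mean square change of log2 CPM was largest between day 0 and day 0.5, at 0.81 per 12 hours (0.52 in log2(TPM + 1)). There, 2 single libraries of day 0 differed by 0.43. It was smallest between day 6 and day 7, at 0.18 (0.12 in log2(TPM + 1) and 0.10 over genes of at least 10 CPM). That value is a step of 24 hours scaled to 12, so a rise and fall within the step would not count. Single libraries differed by 0.43 at day 6 and by 0.41 at day 7.

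**Figure D1:**
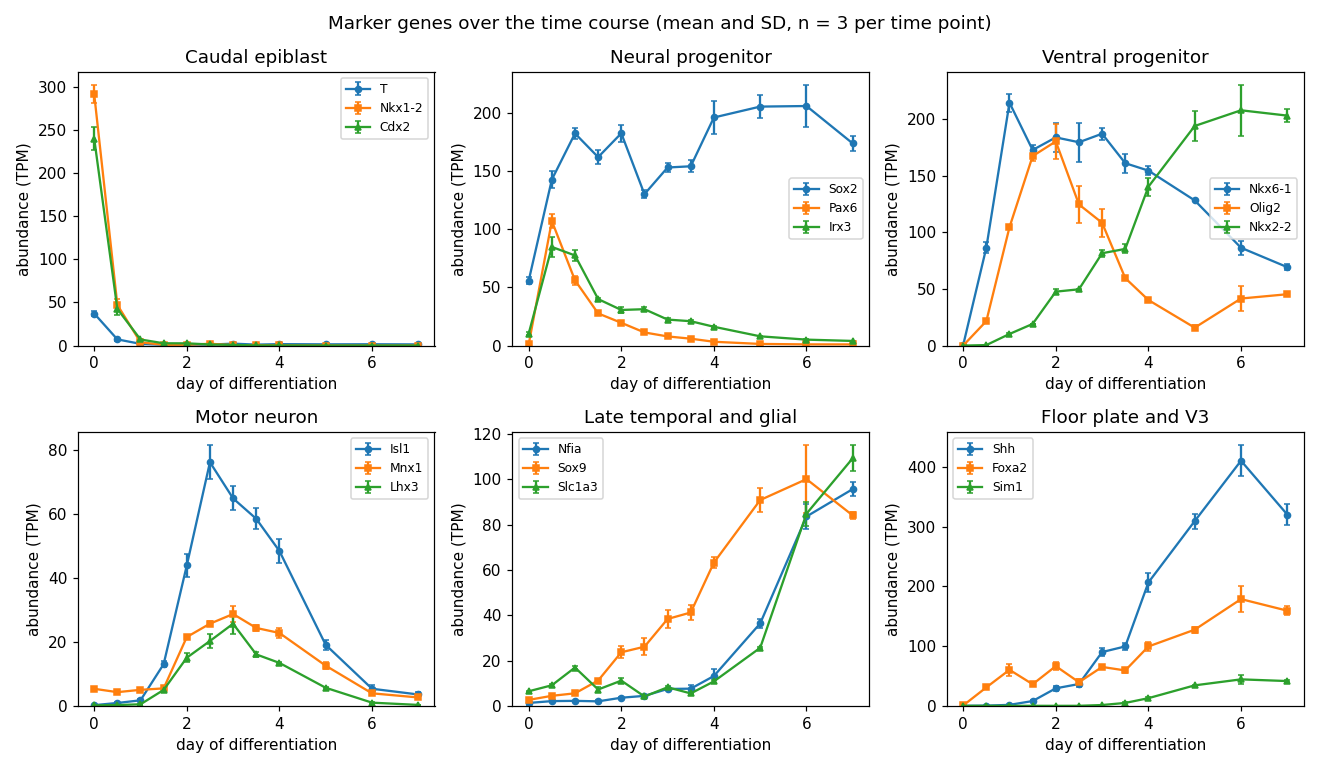
Abundance in TPM (vertical axis) against day of differentiation (horizontal axis) for 18 marker genes in 6 panels, with points for the mean and bars for the SD of 3 replicates. T was highest at day 0, Olig2 at day 2, Isl1 at day 2.5, Shh at day 6 and Nfia at day 7.

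Day 0.5 was compared with day 0, over the first 12 hours of retinoic acid and Hedgehog agonist. Every library after day 0 received both, and there was no untreated group of the same time. The effect of either cannot be told from that of the other or from anything else that changed with time in culture. Targets of both signals rose within 12 hours. Ptch1, the Hedgehog receptor and a direct target of the pathway (ENSMUSG00000021466, chromosome 13, 63508328 to 63573598, minus strand, GRCm38), rose from 21.3 ± 1.13 to 492 ± 4.18 TPM (n = 3 each). Its log2 fold change was 4.42 ± 0.05 (approximate SE, adjusted p = 1.07e-35). Cyp26a1, which degrades retinoic acid (ENSMUSG00000024987, chromosome 19, 37697798 to 37701536, plus strand), rose from 0.54 ± 0.10 to 9.18 ± 0.81 TPM (log2 4.07 ± 0.18, adjusted p = 1.32e-19). Pax6 rose from 1.10 ± 0.10 to 107 ± 6.13 TPM (log2 6.74 ± 0.10, adjusted p = 7.54e-33), while Nkx1-2, a factor of the caudal epiblast, fell from 291 ± 10.7 to 47.3 ± 7.30 TPM (log2 -2.62 ± 0.08, adjusted p = 2.59e-24).

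All 10 Hedgehog target genes rose (camera adjusted p = 3.64e-37), among them Gli1 (log2 3.79), Hhip (3.74) and Ccnd1 (0.94), which at day 1 did not pass (0.13, adjusted p = 0.0862). Of 17 tested retinoic acid response genes 14 rose and 0 fell, with 15 higher when adjusted over the list alone (camera adjusted p = 1.78e-38). Rarb, a retinoic acid receptor, rose by 4.98 ± 0.10 and Dhrs3, a retinaldehyde reductase, by 2.87 ± 0.13 on the log2 scale. The level of Cyp26a1 depended on which time was read, since it was 2.22 ± 0.23 TPM at day 1 and 9.90 ± 0.49 at day 1.5. Set against day 0, day 1 gave 2.01 ± 0.21 for Cyp26a1. Hox paralogues 1 to 4, the anterior part of the Hox clusters, had 11 of 12 members higher and 12 adjusted over the list alone (camera adjusted p = 1.91e-08), with Hoxb3 up by 1.80 and Hoxb4 by 0.85. Hoxb1 did not pass (0.16 ± 0.07, adjusted p = 0.0664) and stood at -1.30 at day 1 against day 0. Hoxb1 passed with no filter on low counts (adjusted p = 0.0171), with only the 6 libraries compared (0.0442) and without day 0 replicate 2 (0.0229) or day 0.5 replicate 3 (0.0204).

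Neural progenitor genes rose in 16 of 20 cases and fell in 3 (camera adjusted p = 9.22e-60), with Sox1 up from 4.16 ± 0.26 to 76.6 ± 3.25 TPM and Sox2 up by 1.36 ± 0.05 on the log2 scale. Ventral progenitor genes rose in 11 of 14 cases and fell in 1 (camera adjusted p = 7.21e-22). Nkx6-1 rose from 0.54 ± 0.11 to 86.6 ± 4.76 TPM (log2 7.31 ± 0.10) and Olig2 from 0.11 ± 0.06 to 21.7 ± 1.64 TPM (log2 7.65 ± 0.29). Genes of the neurogenic transition rose in 15 of 22 cases and fell in 4 (camera adjusted p = 1.04e-08), with Dll1, a Notch ligand, up by 1.24. The counts adjusted over each list alone were the same for these 3 lists.

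Caudal epiblast and neuromesodermal genes fell in 16 of 17 cases and rose in 1 (camera adjusted p = 1.77e-22), with T down to 7.27 ± 1.50 TPM (log2 -2.37 ± 0.20), Cdx2 at -2.50 ± 0.10 and Wnt3a at -2.78 ± 0.23. Fgf8 fell as well (-0.74 ± 0.28, adjusted p = 0.0243), a call that ended without day 0.5 replicate 3 (adjusted p = 0.152) or 1 (0.0649) without day 0 replicate 2 (0.101) or 3 (0.0645), and in log2(TPM + 0.1) (0.235). Tbx6, a paraxial mesoderm factor, did not pass at day 0.5 (-0.37 ± 0.32, adjusted p = 0.341) but was lower at day 1 (-1.00, adjusted p = 0.00902). The paraxial mesoderm list passed upwards, with 4 of 11 genes higher and 1 lower (camera adjusted p = 0.0218; adjusted p = 0.17 with an estimated correlation), a call lost with no filter on low counts (adjusted p = 0.0584), with only the 6 libraries compared (0.0845), without day 0 replicate 1 (0.0573) and with day 1 (0.251). Wnt and Fgf response genes fell in 18 of 19 cases (camera adjusted p = 8.16e-23), among them Axin2, a feedback inhibitor of Wnt signalling (-1.47), and Dusp4 (-1.50). Evx1 (-4.11), Wnt6 (-4.63), Actc1 (-4.05) and Lzts1 (-4.01) were among the largest falls, as were Platr15 (-4.63) and Evx1os (-4.78). Evx1os is antisense to Evx1, and counting by strand is not stated, so both are uncertain. Pluripotency and epiblast genes fell in 15 of 22 cases and rose in 4 (camera adjusted p = 0.000659; adjusted p = 0.199 with an estimated correlation), with Pou5f1 down from 275 ± 10.5 to 43.1 ± 0.38 TPM. Integrated stress response genes fell in 19 of 20 cases (camera adjusted p = 1.3e-17), among them Ddit4 (-2.02) and Asns (-1.82). Endoderm and surface epithelium genes, markers of other cell types, fell in 7 of 11 cases and rose in 4 (camera adjusted p = 0.037; adjusted p = 0.342 with an estimated correlation), with the cadherin gene Cdh1 at -2.47. That list also lost its call without day 0.5 replicate 1 (adjusted p = 0.0739) or 2 (0.0765), with no filter on low counts (0.419) and with only the 6 libraries compared (0.122). Endothelial genes rose in 9 of 15 cases and fell in 4, and the list did not pass (camera adjusted p = 0.111), though it did with day 1 (0.000569) and with no filter on low counts (0.0235). Adjusted over each list alone, these counts were the same.

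In all, 9764 genes (54.3%) changed, 4960 higher and 4804 lower, and 2477 of them by at least 2-fold, 1003 higher and 1474 lower. Every replicate of one time lay above every replicate of the other in 11163 genes, where chance gives 10%. With day 1 in place of day 0.5, an alternative chosen after seeing the data, 11242 genes changed and 1551 were higher by at least 2-fold. The largest fitted rises among genes of at least 10 CPM at day 0.5 were Exosc6, at least 196-fold higher, and ccdc198, at least 119-fold higher, each from 0 counts at day 0 against a floor of 3 counts per library. Exosc6 (chromosome 8, 111056339 to 111057664, plus strand) lies wholly inside Aars (111033144 to 111057664, plus strand) and had 0 counts in 30 of the 36 libraries, so its value is uncertain.

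Day 2 was compared with day 0.5 for the patterning of progenitors and the onset of neurons. Olig2 and neuronal genes rose, and caudal epiblast genes fell. Olig2 (ENSMUSG00000039830, chromosome 16, 91225457 to 91228677, plus strand) rose from 21.7 ± 1.64 to 180 ± 15.4 TPM (n = 3 each, log2 2.94 ± 0.11, adjusted p = 1.28e-21). Nkx2-2, a factor of the most ventral neural progenitors, rose from 0.50 ± 0.07 to 47.7 ± 1.96 TPM (log2 6.57 ± 0.12, adjusted p = 6.15e-30). Neurog2, a proneural factor, rose from 17.2 ± 2.42 to 88.6 ± 8.95 TPM (log2 2.26 ± 0.10, adjusted p = 7.96e-20). Pax6 fell from 107 ± 6.13 to 19.6 ± 1.34 TPM (log2 -2.49 ± 0.07, adjusted p = 6.34e-26).

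Ventral progenitor genes rose in 11 of 14 cases and fell in 1 (camera adjusted p = 2.51e-12), with Shh, the Sonic hedgehog ligand itself, up by 5.94 ± 0.18. Nkx6-1 (0.98 ± 0.06) and Foxa2 (0.94 ± 0.10) were higher too, but against day 1 Nkx6-1 was lower at day 2 (-0.32) and Foxa2 did not pass (0.02, adjusted p = 0.867). Within the neural progenitor list 13 of 20 genes rose and 6 fell (camera adjusted p = 0.0261; adjusted p = 0.246 with an estimated correlation), and the list did not pass against day 1 (0.917), with only the 6 libraries compared (0.108) or with a replicate block (0.0532). Sox1 (-1.44) and Irx3 (-1.58) were among those that fell, and Hes5, a Notch target, was higher by 0.28 ± 0.09 but lower against day 1 (-0.29) and not called without day 2 replicate 2 (0.17, adjusted p = 0.0894). Pax3, a dorsal factor, fell to 0.06 ± 0.04 TPM (-3.80 ± 0.51), and Dbx2, an intermediate factor, did not pass (0.46 ± 0.32, adjusted p = 0.197).

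Neurogenic transition genes rose in 21 of 22 cases (camera adjusted p = 1.96e-22), with Nhlh1 up by 5.11 ± 0.14. Pan-neuronal genes rose in 22 of 24 cases and fell in 1 (camera adjusted p = 3.97e-32), with Tubb3 up from 20.6 ± 1.27 to 335 ± 33.6 TPM and Dpysl3 up by 2.53. Motor neuron genes rose in 17 of 23 cases and fell in 4 (camera adjusted p = 1.65e-13), led by Lhx4, a LIM homeobox gene, at 9.59 ± 0.24. Visceral and hindbrain motor neuron genes rose in 6 of 9 cases and fell in 0 (camera adjusted p = 4.03e-05). The 3 Onecut genes, the early-born neuron temporal factors, all rose (camera adjusted p = 0.000425), with Onecut1 at 3.41. Other large rises were Sst, the somatostatin gene (7.50 ± 0.20), St18 (8.22) and Rasgef1c (6.97). BC024139 rose by a count ratio of 591 (95% interval 163 to 4890), but it overlaps Eppk1 on the same strand and is uncertain. Hox paralogues 5 to 8 rose in 9 of 11 cases and fell in 2 (camera adjusted p = 0.000378), with Hoxb5 up by 2.05. Hoxc6 rose by 1.52 ± 0.20. The counts adjusted over each list alone were the same for these lists.

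Caudal epiblast and neuromesodermal genes fell in 16 of 17 cases (camera adjusted p = 6.46e-17), with Wnt8a at -10.41 ± 0.18 and Cdx1 at -8.95 ± 0.26. Sfrp5, a secreted Wnt inhibitor, fell by 7.05 ± 0.28 on the log2 scale. Hes3, expressed in neuromesodermal progenitors, was lower by a count ratio of 490 (95% interval 135 to 4050). Pluripotency and epiblast genes fell in 17 of 22 cases and rose in 1 (camera adjusted p = 3.31e-09), with Pou5f1 at -3.99, Lin28a at -1.88 and Trh at -8.06. The Hedgehog co-receptor and Gli list fell in all 6 members (camera adjusted p = 0.0019), with Gli2 at -1.78 and Gli3 at -1.15. The retinoic acid response list split, with 9 of 17 genes higher and 7 lower, or 10 and 7 adjusted over the list alone, and did not pass (camera adjusted p = 0.376). Within it Cyp26a1 stood at 4.10 ± 0.39 TPM at day 2, between 9.90 ± 0.49 at day 1.5 and 8.93 ± 0.94 at day 2.5. Glycolysis and hypoxia genes fell in 16 of 22 cases and rose in 4 (camera adjusted p = 4.42e-06; adjusted p = 0.238 with an estimated correlation), with the glucose transporter gene Slc2a3 at -4.69. Integrated stress response genes rose in 17 of 20 cases and fell in 1 (camera adjusted p = 1.48e-10; adjusted p = 0.0865 with an estimated correlation), with Asns up from 147 ± 1.16 to 463 ± 65.5 TPM. Among markers of other cell types, endothelial genes rose in 12 of 15 cases and fell in 2, or 3 adjusted over the list alone (camera adjusted p = 0.00234; adjusted p = 0.471 with an estimated correlation), and against day 1 the list did not pass (0.183). Pecam1 went from 1.12 ± 0.09 to 11.6 ± 3.64 TPM and Cdh5 from 2.46 ± 0.93 to 15.3 ± 2.84 TPM. Blood and microglia genes rose in 6 of 7 cases, and the list did not pass (camera adjusted p = 0.156) except with no filter on low counts (0.0419). Endoderm and surface epithelium genes went the other way, with 9 of 11 lower and 1 higher (camera adjusted p = 0.000213, and 0.0752 with an estimated correlation).

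In all, 12219 genes (67.9%) changed, 6101 higher and 6118 lower, and 4019 by at least 2-fold, 2179 higher and 1840 lower. The groups did not overlap in 12776 genes, where chance gives 10%. With day 1 in place of day 0.5, 9764 genes changed, 8178 of them shared with the count above, and 2263 by at least 2-fold. That count equals the one for day 0.5 against day 0 by coincidence, since it comes from another comparison.

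Day 4 was compared with day 2 for the maturing of neurons. Neuronal and synaptic genes rose, genes of the cell cycle fell, and the progenitor factor Olig2 fell. Tubb3 (ENSMUSG00000062380, chromosome 8, 123411424 to 123422015, plus strand) rose from 335 ± 33.6 to 1101 ± 69.95 TPM (n = 3 each, log2 1.52 ± 0.07, adjusted p = 5.58e-20). Nefl, a neurofilament gene, rose from 61.5 ± 5.67 to 716 ± 35.5 TPM (log2 3.35 ± 0.08, adjusted p = 4.37e-27). Olig2 fell from 180 ± 15.4 to 40.3 ± 0.97 TPM (log2 -2.36 ± 0.11, adjusted p = 2.08e-19) and Neurog2 from 88.6 ± 8.95 to 32.3 ± 1.58 TPM (log2 -1.66 ± 0.10, adjusted p = 1.15e-16).

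All 24 pan-neuronal genes rose (camera adjusted p = 3.36e-37), with Elavl3, an RNA-binding protein of neurons that overlaps Gm49318 on the same strand, up by 1.20. Synapse and neurotransmission genes rose in 26 of 28 cases and fell in 1 (camera adjusted p = 1.81e-23). Motor neuron genes rose in 18 of 23 cases and fell in 1 (camera adjusted p = 3.06e-08). The vesicular acetylcholine transporter gene Slc18a3 rose by 1.10 ± 0.07 and Chat, which makes acetylcholine, by 0.79 ± 0.11. The spans of these 2 genes overlap on the same strand, with no shared exon in GENCODE M21. Isl1 (-0.09 ± 0.09, adjusted p = 0.392) and Mnx1 (-0.12 ± 0.07, adjusted p = 0.152) did not pass, though Mnx1 did without day 4 replicate 2 (-0.19, adjusted p = 0.0403). Lhx3 fell (-0.34 ± 0.09, adjusted p = 0.002), a call lost in log2(TPM + 1), with -0.15 and adjusted p = 0.144, and in log2(TPM + 0.1), with adjusted p = 0.416. Spinal interneuron genes rose in 12 of 21 cases and fell in 5 (camera adjusted p = 0.00568), with Sim1, a marker of V3 interneurons, up from 0.10 ± 0.04 to 12.9 ± 2.05 TPM and Lhx1 up by 4.19. Neurog3, a proneural factor, had the largest rise among genes named by the rule on size, from 0.18 ± 0.15 to 72.9 ± 12.8 TPM (log2 8.42 ± 0.24). Scg2 (6.21), Tnr (6.68), Bcl11b (5.73) and Pcp4 (6.15) followed, and Pcp4 overlaps Igsf5 on the same strand. All 11 Hox paralogues 5 to 8 rose (camera adjusted p = 6.91e-07), with Hoxb6 at 1.50. The counts adjusted over each list alone were the same for these lists.

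Ventral progenitor genes rose in 9 of 14 cases and fell in 5 (camera adjusted p = 0.000142; adjusted p = 0.114 with an estimated correlation), and the list did not pass with only the 6 libraries compared (0.0936). Those that rose included Spon1 (2.71) and Ntn1 (1.26), which are known from the floor plate. Hedgehog target genes fell in 6 of 10 cases and rose in 4 (camera adjusted p = 0.000142), with Gli1 at -3.59 and Ptch1 at -1.18, while Nkx2-2, also on that list, rose by 1.29. Sox2 (-0.09 ± 0.05, adjusted p = 0.0981) did not pass, except without day 2 replicate 1 (adjusted p = 0.0285) or day 4 replicate 1 (0.0417). Hes5 fell by 2.16 ± 0.10 on the log2 scale. Dll1 was called lower (-0.12 ± 0.05, adjusted p = 0.0213) but was higher in log2(TPM + 1) (0.18, adjusted p = 0.00311), so its direction is not settled. The call also ended with only the 6 libraries compared (adjusted p = 0.0581), without day 2 replicate 2 (adjusted p = 0.0789) or 3 (0.0611) and without day 4 replicate 1 (0.061) or 3 (0.0841). Astroglial and gliogenic genes rose in 15 of 26 cases and fell in 6 (camera adjusted p = 0.00175; adjusted p = 0.0752 with an estimated correlation), with Fabp7 up from 53.7 ± 2.35 to 1667 ± 148 TPM.

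All 25 S phase genes fell (camera adjusted p = 6.52e-19; adjusted p = 0.0511 with an estimated correlation), with Mcm6 at -1.34. All 26 G2 and M phase genes fell (camera adjusted p = 8.1e-09; adjusted p = 0.289 with an estimated correlation), with Mki67 at -0.55 ± 0.08 and Top2a at -0.70. Integrated stress response genes fell in 18 of 20 cases, or 19 adjusted over the list alone (camera adjusted p = 6.61e-21). Chac1 (-4.50 ± 0.22) and Trib3 (-3.91 ± 0.20) were among the largest falls, with Slc7a3, a cationic amino acid transporter gene (-4.83), Grb7 (-4.47) and Mobp (-3.70). Cytosolic ribosomal protein genes fell in 31 of 33 cases and rose in 0, or 1 adjusted over the list alone (camera adjusted p = 3.03e-18; adjusted p = 0.129 with an estimated correlation), with Rps2 at -1.10. Among markers of other cell types, blood and microglia genes fell in 5 of 7 cases (camera adjusted p = 0.0242; adjusted p = 0.238 with an estimated correlation), with the embryonic globin gene Hba-x down from 19.2 ± 6.10 to 0.12 ± 0.05 TPM. Endothelial genes fell in 11 of 15 cases and rose in 1, and the list did not pass (camera adjusted p = 0.0794), though it did with no filter on low counts (0.0025), with only the 6 libraries compared (0.017) and without day 2 replicate 2 (0.0205). Fibroblast and mesenchyme genes rose in 12 of 18 cases and fell in 1 (camera adjusted p = 0.00486; adjusted p = 0.335 with an estimated correlation), with Col3a1 up by 2.42. Where no other count is given, that adjusted over the list alone was the same.

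In all, 11683 genes (64.9%) changed, 5957 higher and 5726 lower, and 3257 by at least 2-fold, 2050 higher and 1207 lower. The groups did not overlap in 11741 genes, where chance gives 10%. Of the calls 51% were higher in the main fit, 51.8% with median-of-ratios scaling and 68.6% with limma on log2(TPM + 1), where the median of all genes moved from 0.01 to 0.13.

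Day 7 was compared with day 4 for the late culture. Motor neuron genes fell, and glial and late temporal genes rose. Isl1 (ENSMUSG00000042258, chromosome 13, 116298281 to 116309689, minus strand) fell from 48.5 ± 3.89 to 3.57 ± 0.79 TPM (n = 3 each, log2 -3.89 ± 0.12, adjusted p = 1e-23) and Mnx1 from 22.8 ± 1.45 to 2.64 ± 0.38 TPM (log2 -3.18 ± 0.10, adjusted p = 2.5e-24). Nfia, a factor of late-born neurons and of gliogenesis (ENSMUSG00000028565, chromosome 4, 97772734 to 98118874, plus strand), rose from 13.2 ± 2.92 to 95.8 ± 3.03 TPM (log2 2.52 ± 0.06, adjusted p = 1.86e-27). Slc1a3, a glutamate transporter gene of astroglia, rose from 10.8 ± 0.61 to 109 ± 5.73 TPM (log2 3.30 ± 0.05, adjusted p = 1.92e-31).

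Motor neuron genes fell in 16 of 23 cases and rose in 7 (camera adjusted p = 1.28e-11), with Lhx3 at -5.41 ± 0.16, Lhx4 at -5.54, Isl2 at -5.56 and Chat at -2.91 ± 0.13. Neurog2 (-4.89), Nkx2-9 (-4.79) and Sst (-4.65) were also among the largest falls. Neurogenic transition genes fell in 17 of 22 cases and rose in 4 (camera adjusted p = 1.08e-06; adjusted p = 0.0752 with an estimated correlation). All 3 Onecut genes fell (camera adjusted p = 0.0017), and all 6 late-born neuron temporal factors rose (camera adjusted p = 3.74e-09), with Neurod2 up from 0.06 ± 0.05 to 13.9 ± 0.87 TPM and Nfib by 2.26 ± 0.10. Synapse and neurotransmission genes rose in 27 of 28 cases (camera adjusted p = 8.99e-20), with Snap25 up by 0.84 ± 0.09 and Slc17a6, a vesicular glutamate transporter gene, by 3.84 ± 0.17. Gad1, which makes GABA, was called higher (2.47 ± 0.61, adjusted p = 0.000662) at a level of only 0.29 ± 0.16 TPM, and the call was lost in log2(TPM + 1) (0.29, adjusted p = 0.0657). Other large rises were Olig3 (5.82), Grm7 (6.14) and Pdyn, the prodynorphin gene, with a count ratio of 328 (95% interval 112 to 1590).

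Astroglial and gliogenic genes rose in 21 of 26 cases and fell in 2 (camera adjusted p = 1.39e-16), with Fabp7 up by 0.88 ± 0.05 and Sox9 by 0.36 ± 0.08. Oligodendroglial genes rose in 13 of 15 cases (camera adjusted p = 4.6e-06), with Sox10 up from 0.07 ± 0.04 to 28.5 ± 1.12 TPM, Bcas1 by 6.23 and Pdgfra, a receptor of oligodendrocyte precursors, by 1.75 ± 0.13. All 25 S phase genes (camera adjusted p = 5.81e-34) and all 26 G2 and M phase genes (camera adjusted p = 9.57e-48) fell, with Top2a at -2.08 ± 0.06 and Mki67 at -2.10. Retinoic acid response genes fell in 13 of 17 cases and rose in 2 (camera adjusted p = 8.81e-05; adjusted p = 0.0659 with an estimated correlation), with Crabp2 at -3.63. Hedgehog target genes fell in 7 of 10 cases and rose in 3 (camera adjusted p = 0.00921; adjusted p = 0.101 with an estimated correlation, and 0.0845 with only the 6 libraries compared), with Ptch1 at -0.70. Hypoxia and glycolysis genes rose in 21 of 22 cases (camera adjusted p = 3.84e-15), with Ldha, the lactate dehydrogenase gene, up from 119 ± 4.72 to 972 ± 123 TPM. Proteasome subunit genes fell in all 27 cases (camera adjusted p = 0.000344; adjusted p = 0.465 with an estimated correlation), with Psmc1 at -0.41. Cytosolic ribosomal protein genes fell in 32 of 33 cases (camera adjusted p = 2.85e-08; adjusted p = 0.382 with an estimated correlation), with Rpl4 at -0.60. Among markers of other cell types, all 18 fibroblast and mesenchyme genes rose (camera adjusted p = 1.82e-09), with Col1a1 up from 6.99 ± 0.19 to 89.7 ± 4.12 TPM (log2 3.59 ± 0.13) and Col3a1 by 2.69. Endothelial genes fell in 11 of 15 cases, or 12 adjusted over the list alone, and rose in 1, and the list did not pass (camera adjusted p = 0.234), though it did with only the 6 libraries compared (0.00874) and with no filter on low counts (0.0161). The counts of the other lists were the same adjusted over the list alone.

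In all, 11933 genes (66.3%) changed, 6023 higher and 5910 lower, and 3670 by at least 2-fold, 2414 higher and 1256 lower. The groups did not overlap in 12414 genes, where chance gives 10%.

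**Figure D2:**
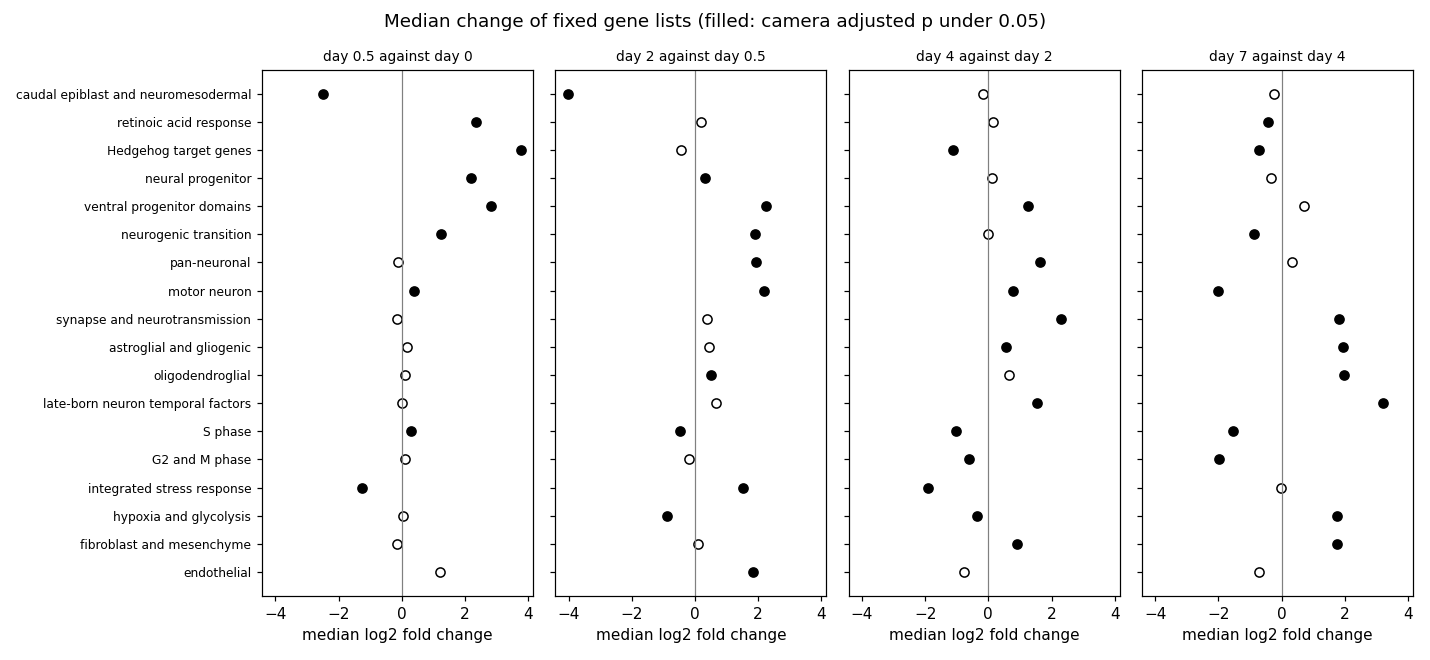
Median log2 fold change (horizontal axis) of 18 of the 39 fixed gene lists (vertical axis) in the 4 comparisons, 1 panel each and on 1 scale. Filled points are lists with a camera adjusted p under 0.05, among them the motor neuron list at -2.01 for day 7 against day 4. Over all 39 lists 74 of 156 tests passed, and 37 with an estimated correlation.

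**Figure D3:**
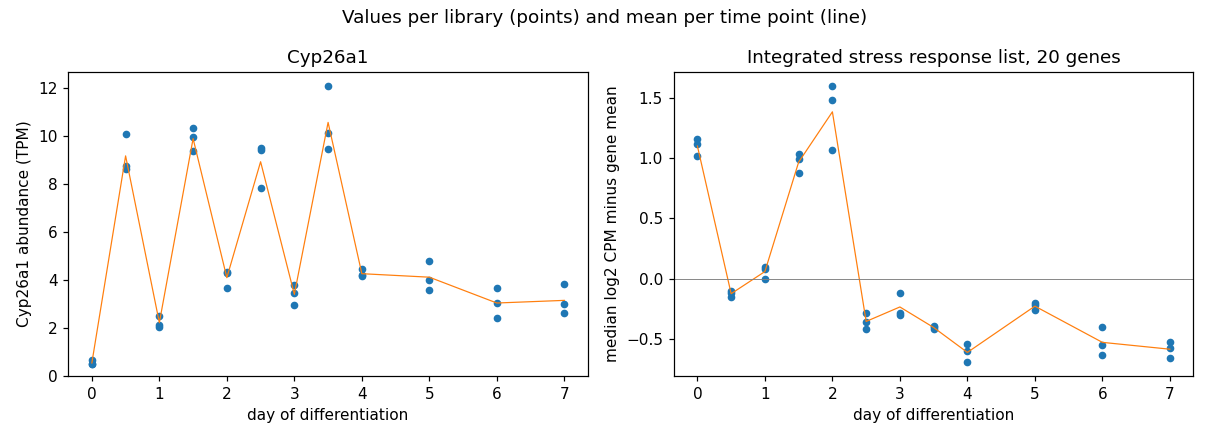
Values of the 36 libraries (points) and the mean per time point (line) against day of differentiation: Cyp26a1 abundance in TPM on the left, and on the right the median over the 20 integrated stress response genes of log2 CPM minus each gene's mean. Cyp26a1 stood at 9.18 TPM at day 0.5, 2.22 at day 1 and 9.90 at day 1.5.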

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

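The test of retinoic acid response genes against the time of sampling, both tests of the fibroblast genes and the contrast between neighbouring time points were chosen after the result was seen.

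The libraries of days 1.5, 2.5 and 3.5, which enter none of the 4 comparisons, stood apart from the whole days around them. A weighted contrast set days 1.5, 2.5 and 3.5 against days 1, 2, 3 and 4. Its weights were largest at day 2.5, then at days 2 and 3, and smallest at days 1 and 4. Its values therefore mostly compare day 2.5 with days 2 and 3. In it 8296 of 17990 genes passed. Of these, 6775 kept 1 sign at days 1.5, 2.5 and 3.5, each set against the days beside it, 3598 higher and 3177 lower. These signs come from the same libraries that selected the genes, and a profile that bends steadily also keeps 1 sign. No share to be met without alternation was worked out, so the count is not separate support for it. The lowest Cyp26a1 TPM of the 9 libraries at days 1.5, 2.5 and 3.5 was 7.85, where the control libraries of day 0 had a mean of 0.54 ± 0.10 and those of day 1 2.22 ± 0.23. Day 0.5, outside that contrast, had 9.18 ± 0.81, and it enters 2 of the 4 comparisons, which set it against whole days. Of 39 lists 21 passed (7 with an estimated correlation), among them proteasome subunits (median 0.25), ventral progenitor domains (-0.43) and Hedgehog targets (-0.34). The integrated stress response list passed too (median -0.59, camera adjusted p = 4.75e-19), yet it was high at both day 1.5 and day 2 and low at day 2.5. A single rise and fall can therefore pass this contrast, and a list that passed need not alternate.

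None of the values excludes any of 3 explanations of this alternation. Hedgehog targets moved opposite to the retinoic acid response genes, but how the agonist acts between changes of medium was not measured, so this does not decide the first. Time since the daily change of medium is open, with the retinoic acid response list at a median of 0.31, at percentile 100 of 10000 random lists matched on expression (0.30 without the Cyp26 genes), but the pattern had been noticed through Cyp26a1, and Hedgehog targets, whose agonist was given with retinoic acid, moved the other way. A circadian clock in step with the hour of harvest is also open, since 17 clock genes had a median size of 0.44, also at percentile 100, with 3 alternating up and 10 down. GC content showed a weak relation across genes (Spearman rho -0.168), between the bounds set for and against a bias of this kind. Gene length (Spearman rho 0.048) was under the lower bound, on the side against a bias. A library batch without such a bias was not tested. The labels used here give no hour of medium change or harvest and no library batch, so the 3 stay open.

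Integrated stress response genes were higher at days 1.5 and 2 than at days 1 and 2.5, with a median difference of 1.19 and all 20 genes higher, among them Chac1 (3.58 ± 0.14) and Trib3 (3.21 ± 0.13), and the list was high at day 0 as well. Stress of the endoplasmic reticulum would raise its chaperones, but 15 such genes had a median of -0.13, with 0 higher and 11 lower. Scaling would end the difference, but the lower median under 2 other scalings was 1.09. What stays open is a shortage of amino acids or another signal to the same pathway, or a batch, and neither was tested.

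All 18 fibroblast and mesenchyme genes rose from day 4 to day 7. Feeder cells left from the stem cell culture would not exceed their level at day 0 if their share had not grown. The median of the list at day 7 was 2.30 above day 0, with 16 of 18 genes higher. Values are shares of a library, so a grown share of such cells is not excluded. A lower share of neural cells could raise markers of other cell types. Endothelial genes fell in 11 of 15 cases and rose in 1. They had also fallen in 11 of 15 cases from day 2 to day 4, so their fall cannot decide this. Endoderm and surface epithelium genes fell in 6 of 11 cases and rose in 2, while neural crest genes rose in 7 of 12 and fell in 1. Neither of these 2 lists passed (camera adjusted p = 0.172 and 0.271). For the endothelial genes the criterion first written, the camera test of the list, did not pass (adjusted p = 0.234, and 0.00874 with only the 6 libraries compared). The count of endothelial genes was chosen after that was seen. A change in the shares of the cell types, in the mesenchymal cells themselves or in the neural cells is a hypothesis that these values leave open. No batch labels were given.

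For each comparison the 6 libraries make 10 splits, too few for a share under 0.05. The real split, the only 1 as large in each case, gave 9764, 12219, 11683 and 11933 genes, and the highest of the other splits 0, 0, 2 and 2. Every other split mixes 2 time points within a group, which widens the spread. Its low count follows from that and does not weigh chance.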

How the results depend on the processing

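The fit without days 1.5, 2.5 and 3.5 and day 1 in place of day 0.5 were chosen after seeing the data. The counts of all changed genes stayed within 1.5 times of those reported under every alternative run. Among named genes 4460 values kept the call, and also the direction unless neither fit passed. A further 59 lost the call, 8 gained it and 10 reversed, which means a change of sign where at least 1 of the 2 fits passed. Of the list tests 1940 were the same, 104 passed only under the alternative and 62 lost the call. Of the days of highest mean 68 were the same and 8 moved.

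List tests passing went from 74 to 37 with an estimated correlation and 135 with fry. Fry asks whether a list changed at all, while camera compares it with the other genes, so the 135 answer another question. In log2(TPM + 1), which understates low genes, the genes changed, higher and lower by at least 2-fold were 957, 408 and 549 (day 0.5 against day 0), 1831, 1196 and 635 (day 2 against day 0.5), 1632, 1332 and 300 (day 4 against day 2) and 2169, 1516 and 653 (day 7 against day 4). Genes lower at day 4 than at day 2 numbered 3525 there and 3524 in log2(TPM + 0.1), of which 704 by at least 2-fold, and the median of all genes rose to 0.13 and 0.19. With day 1 in place of day 0.5, 1551 genes were higher than at day 0 by at least 2-fold, and 2263 differed from day 2 by as much, 1377 higher and 886 lower. Reversed values were Tcf4 at day 0.5 (0.043 and 0.044 in log2(TPM + 1) and log2(TPM + 0.1), 0.10 with day 1), Dll1 at day 4 (0.18 with both), and with day 1 Hoxb1 (-1.30), Lin28b (-0.026), Nkx6-1 (-0.32), Hes5 (-0.29) and Mbp (0.34). The Tcf4 values (adjusted p = 0.666, 0.652 and 0.0671 in that order) and the Lin28b value (0.724) did not pass under the alternative, so they are lost calls with a changed sign. Hoxb1 had not passed in the main fit. The day 1 values come from another time point. Otherwise the cause was not tested.

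Leaving out each replicate, 8895 to 9249, 11625 to 11833, 11036 to 11176 and 11289 to 11470 genes changed in the 4 comparisons, and 73 to 78 list tests passed. The days of highest mean of the 19 profile genes held for 16 to 19, and the largest step was 0.83 in each; it was 0.61 over genes of at least 10 CPM and 0.52 in log2(TPM + 1). With the replicate number as a block, 9754, 12174, 11640 and 11892 genes changed and 73 list tests passed, the neural progenitor list at day 2 losing its call (adjusted p = 0.0532). The numbers were not treated as pairing: every pair correlated over 0.1 at 3 of 6 CPM floors for day 0.5 against day 0 and at 0 of 6 for the others, and this was decided with the floors and the blocked counts already seen. Without days 1.5, 2.5 and 3.5 in the fit, 9603, 12086, 11528 and 11783 genes changed. Changes of 1.5-fold were missed in a share of simulated genes, so a gene that did not pass may still differ.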

Other observations

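The tests of Hox onset and of Hprt were written before their results were seen.

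Hba-x and Hbb-bh1, embryonic globin genes of primitive red cells, were listed at 0 at day 0, reached 19.2 ± 6.10 and 15.8 ± 6.16 TPM at day 2 (n = 3), and stood at 0.12 ± 0.05 and 0.20 ± 0.14 TPM at day 4. The endothelial genes Pecam1 and Cdh5 were highest at day 3, at 24.6 ± 1.23 and 35.0 ± 3.55 TPM. They were still at 11.6 ± 1.58 and 15.9 ± 1.11 TPM at day 7, where Hba-x and Hbb-bh1 were listed at 0.

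Sst was 0.69 ± 0.16 TPM at day 0.5, 301 ± 28.8 at day 2.5 and 2.31 ± 0.66 at day 7. Neurog3 stayed below 1 TPM on average up to day 2.5, reached 178 ± 21.4 TPM at day 5 and was 57.4 ± 2.27 at day 7, the last time point.

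Hox genes may start in the order of their place in the cluster, as is known from the embryo. Across 26 Hox genes with a mean of at least 1 TPM, paralogue number and the first day at 0.5 of the highest mean had a Spearman rho of 0.56 (two-sided permutation p = 0.00334), which is across genes, and genes are not independent replicates. Hoxb9, which was past that level at day 0, and Hoxa9, at day 0.5, were exceptions.

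HM1 is known as a line without a working Hprt gene, and low Hprt transcripts are consistent with that: the highest Hprt level of the 36 libraries was 1.69 TPM.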
